A study of Homo sapiens and Mus musculus with 15 samples.

How the data were processed

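RNA was measured by sequencing in 15 libraries of 2 myeloma lines, in 5 groups of 3. The mouse line 5TGM1 came from a plasma cell tumour passaged in mice, and RPMI-8226, called 8226 here, came from a human plasma cell myeloma. The groups were naive 5TGM1, bortezomib-resistant 5TGM1, naive 8226, bortezomib-resistant 8226 and carfilzomib-resistant 8226. Per the labels' protocols, the resistant lines were raised over months of culture in rising drug, were kept in 20 nM bortezomib (5TGM1), 10 nM bortezomib (8226) or 10 nM carfilzomib (8226), and were taken off the drug 5 days before RNA was extracted. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Each resistant group stands alone for its drug and line. Changes that came with deriving that group cannot be told apart from resistance or from the drug.

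The authors deposited a gene count table for each library, in the layout that STAR writes. STAR is named in the submitters' processing notes, and its version is not given in the sources used here. The notes also name the builds mm10, hg19, GRCm38 and GRCh37 without assigning them to files, and the release of the gene annotation is not given in the sources used here. The deposited values are whole-number read counts per gene symbol, not normalized, in 3 columns: without regard to strand, on the strand of the gene, and on the opposite strand. The labels do not describe a strand-marking kit. The values themselves put almost all reads in the last of these columns, with 1.43% to 2.12% of stranded gene reads in the other, so column 4 was used throughout. There were 23329 genes in each mouse table and 23346 genes in each human one. The first 4 rows of a table are totals of reads outside genes, and they stayed out of library sizes and tests. Reads that mapped to several places were set aside by the counting and made up 15.3% to 16.3% of reads in the mouse libraries and 8.95% to 10.9% in the human ones. Genes with near-identical copies are therefore undercounted, and their values are uncertain. This applies to MHC class I and class II genes, histones, ribosomal protein genes and the GAGE, MAGE and endogenous retroviral families. Unmapped reads made up 5.62% to 6.04% (mouse) and 1.04% to 1.67% (human). Reads on no annotated gene made up 10.6% to 12.0% and 10.4% to 16.6%, and reads on several genes 0.602% to 0.633% and 0.951% to 1.14%. No mitochondrially encoded gene was listed, so that class was not analysed here.

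Reads on genes totalled 49097494 to 72288680 per mouse library and 31709636 to 58419576 per human library. At that depth 3 counts, the limit that a count of 0 allows at 95% confidence, correspond to 0.0415 to 0.0611 CPM in a mouse library and 0.0514 to 0.0946 CPM in a human one. Intervals and limits of this kind cover counting error only.

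Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries of each line were scaled by TMM, whose factors ran from 0.996 to 1.00 (mouse) and 0.937 to 1.08 (human), and genes with low counts were removed by filterByExpr. This left 11974 mouse genes and 13910 human genes. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. Differences were tested by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. All 9 human libraries shared a fit. SEs of log2 fold changes were derived from the F statistic. The 4 comparisons were bortezomib-resistant with naive 5TGM1, bortezomib-resistant with naive 8226, carfilzomib-resistant with naive 8226, and carfilzomib-resistant with bortezomib-resistant 8226. A test of the difference between the bortezomib-resistance changes of the lines was fitted over genes with the same symbol in mouse and human, ignoring case. Such a match of symbols is not an orthology table.

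Gene lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. The 40 lists and 15 key genes were fixed before the data were examined, and lists with fewer than 5 tested members were not tested. Beside each list's count over all genes, the count adjusted over the list alone is given where it differs. Splits of the libraries that mix the groups also called lists at the preset correlation, as given in the closing observations.

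The genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap between libraries. It adds the key genes whatever their value, the 2 to 4 called members of a described list that moved most and reach 10 CPM, and up to 10 genes per direction for each overlap. Unnamed loci and predicted genes meeting the rule could be left out. Genes whose level could show a donor's sex were also left out, 3 in the comparison of carfilzomib-resistant with naive 8226 and 3 in that of the resistant 8226 lines. The genes named in the closing observations were chosen after their values were seen, whether or not the rule covers them.

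A fold against a group with 0 counts in all 3 libraries is a lower bound, computed against a floor of 3 counts over that group. With 1 to 3 counts in the group, the ratio is given with its 95% counting interval.

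Alternatives fixed before the data were examined were RLE factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fold change of at least 2, a test against a fold change of 1.5, fits of only the groups compared, a replicate block, and leaving out each library in turn. Unstranded counts were added after the data were seen. Other splits of the libraries, 10 for each comparison and up to 100 for overlaps, were refitted. The human reference at hand was GRCh38, which is not a build the notes name, so it was used only for gene names and for which genes neighbour each other. No mouse reference was used here, and no coordinates are given.

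The procedure was tested on simulated data with 200 changed genes drawn from the real means and library sizes. In the real comparisons 67.2% to 79.8% of genes were called. The shares recovered and the false calls below therefore do not cover data in which most genes change. In simulations of the 5TGM1 comparison, over 11953 genes, 97.0% of genes changed by a log2 of 0.5 and 100% of those changed by 1 or 2 were recovered, with 9 false calls. For bortezomib-resistant with naive 8226, over 13363 genes, the shares were 90.9%, 95.5% and 100%, with 7 false calls. For carfilzomib-resistant with naive 8226, over 13348 genes, they were 97.0%, 100% and 100%, with 13 false calls. For the resistant 8226 lines, over 12397 genes, they were 89.4%, 100% and 100%, with 14 false calls. The test of the difference between lines, over 11709 genes, recovered 99% and 100% of differences of 1 and 2, with 3 false calls.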

Results

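Transcriptomes of drug-naive and proteasome-inhibitor-resistant myeloma cells were compared in a mouse line, 5TGM1, and a human line, 8226. Bortezomib, a peptide boronate, and carfilzomib, a peptide epoxyketone, both bind the proteasome subunit encoded by PSMB5. Each of the 5 groups had 3 libraries. Reads on genes ran from 49097494 to 72288680 per library in naive and 49157882 to 57896736 in bortezomib-resistant 5TGM1. In 8226 they ran from 39032731 to 46874782 (naive), 31709636 to 34339788 (bortezomib-resistant) and 41964250 to 58419576 (carfilzomib-resistant), so the bortezomib-resistant group was the shallowest. Libraries of a group correlated across genes at 0.995 to 0.998. Between groups the correlations were 0.969 to 0.970 for the mouse pair and 0.813 to 0.821 for naive with bortezomib-resistant 8226. They were 0.868 to 0.871 for naive with carfilzomib-resistant 8226 and 0.859 to 0.864 for the resistant 8226 lines. Genes are not independent replicates in these values. Library pairs of a group differed by more than sampling noise, with chi-square values per degree of freedom of 3.84 to 24.4. Levels below are mean CPM ± SD (n = 3 per group), changes are log2 fold changes ± SE, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or for gene lists from camera.

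The first comparison asked how bortezomib-resistant 5TGM1 cells differed from naive ones. Resistant 5TGM1 cells held less transcript of the inducible proteasome subunit genes Psmb8, Psmb9 and Psmb10 and of the MHC class I pathway, which presents proteasome products. Psmb8, an inducible catalytic subunit, fell from 395 ± 11.8 to 134 ± 2.24 CPM (-1.56 ± 0.0405, adjusted p = 7.0e-15), and H2-K1, a classical class I heavy chain, fell from 3520.3 ± 130.0 to 721 ± 9.93 CPM (-2.29). Psmb5, the subunit bortezomib binds, fell 1.80-fold, from 71.3 ± 3.50 to 39.6 ± 0.218 CPM (-0.85 ± 0.0453, adjusted p = 7.2e-11), while 12 of the 14 constitutive 20S core genes rose.

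All 5 tested genes of the immunoproteasome list fell (median -1.23, adjusted p = 3.2e-13, and adjusted p = 0.177 with an estimated correlation). Psmb9 fell from 85.7 ± 4.30 to 31.0 ± 0.566 CPM and Psmb10 by 0.96 ± 0.0495, and Psme1 (-1.23) and Psme2 (-1.17), which encode the PA28 activator, also fell. Of the MHC class I and antigen-processing genes, 8 of 12 fell and 2 rose (9 and 2 adjusted over the list alone) (median -0.93, adjusted p = 2.1e-17, and adjusted p = 0.0259 with an estimated correlation), and this was the only list of the comparison whose call held with an estimated correlation. Nlrc5, a transcriptional activator of class I genes, fell from 57.2 ± 2.81 to 7.02 ± 0.0537 CPM, H2-D1 fell by 1.95, and Tap1, a subunit of the peptide transporter, fell by 1.79. Reads of H2 genes can be shared with near-identical copies. Of the MHC class II genes, 3 of 7 rose and 3 fell (3 and 4 adjusted over the list alone) (adjusted p = 0.675), with H2-Eb1 down from 62.3 ± 4.16 to 10.3 ± 0.473 CPM and H2-DMb1 up by 1.39. Of the interferon-induced genes, 14 of 28 rose and 12 fell (median 0.19, adjusted p = 0.132), with Rsad2 (2.19), Oasl1 (1.79) and Isg15 (1.36) up and Parp14 (-1.57) down. Only 3 macrophage markers were tested, of which Cd68 (0.49) and Mrc1 (0.40) rose and Mpeg1 (-1.30) fell.

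In the 20S core, Psmb1 (0.50), Psmb3 (0.40) and Psma6 (0.31) rose against the fall of Psmb5, and the list was not called (median 0.25, adjusted p = 0.204). Of the 19S cap genes, 11 of 22 rose and 2 fell (adjusted p = 0.675), with Psmd6 (-0.95) and Psmc6 (-0.68) down and Psmd4 (0.45) up. Of the hypoxia genes, 12 of 16 rose and 2 fell (median 0.56, adjusted p = 1.9e-07, and adjusted p = 0.141 with an estimated correlation). Egln3, a prolyl hydroxylase that acts on HIF proteins, rose from 0.762 ± 0.0744 to 14.7 ± 0.243 CPM, and Bnip3 (1.48), P4ha2 (1.24) and Ankrd37 (1.01) rose. Of the integrated stress response genes, 18 of 29 rose and 2 fell (median 0.17, adjusted p = 0.00606, and adjusted p = 0.625 with an estimated correlation), with rises of Ddit4 (1.47), Ero1l (0.81), Trib3 (0.76) and Pycr1 (0.71). Ddit3, encoding CHOP, rose by 0.45 ± 0.0509, and Atf4 was at 749 ± 23.9 CPM in naive and 766 ± 12.9 CPM in resistant libraries (adjusted p = 0.469).

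Of the cell cycle and E2F target genes, 33 of 40 fell and 3 rose (median -0.31, adjusted p = 0.000146, and adjusted p = 0.127 with an estimated correlation), including Mcm10 (-0.57), Ccnb1 (-0.55), Cdc20 (-0.55) and Top2a (-0.52). Of the MYC target and ribosome biogenesis genes, 19 of 28 fell and 2 rose (median -0.23, adjusted p = 0.00510, and adjusted p = 0.179 with an estimated correlation), including Gnl3 (-1.17), Dkc1 (-0.66), Srm (-0.65) and Npm1 (-0.54), and Myc fell by 0.15 ± 0.0370. Of the replication-dependent histone genes, 9 of 15 fell and 0 rose (median -0.69, adjusted p = 0.0328, and adjusted p = 0.770 with an estimated correlation), including Hist1h1c (-1.24) and Hist1h2bc (-1.19). Cytosolic ribosomal protein genes went the other way, as 41 of 54 rose and 3 fell (43 and 3 adjusted over the list alone), but the list was not called (median 0.18, adjusted p = 0.0532). In the IGF1, HGF and IL6 signalling list 4 of 10 rose and 4 fell (adjusted p = 0.0369, and adjusted p = 0.653 with an estimated correlation). Its median was -0.05 and its mean -0.95, with Igf2r, a receptor that clears IGF2, going from 85.3 ± 7.76 to 0.102 ± 0.0580 CPM. Dusp6 (-0.58) and Stat3 (-0.52) fell and Irs2 (0.52) rose.

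Of the unfolded protein response genes, 16 of 33 rose and 11 fell, with a median of 0.05 and a mean of -0.01 where the test pointed up (adjusted p = 0.886). Xbp1 fell by 0.41 ± 0.0423 and Dnajc3 by 1.20, while Pdia4 rose by 0.61 and Hspa5, the chaperone BiP, by 0.13 ± 0.0396 (adjusted p = 0.00783). Of the plasma cell identity genes, 9 of 18 rose and 5 fell (10 and 5 adjusted over the list alone) (median 0.26, adjusted p = 0.423). Pou2af1 (1.20), Igj, the immunoglobulin joining chain (0.70), and Sdc1, encoding CD138 (0.63 ± 0.0420), rose. Pim2 fell by 1.29 and Prdm1, encoding Blimp-1, by 0.50 ± 0.0437, while Irf4 was at 772 ± 22.7 and 825 ± 30.2 CPM (adjusted p = 0.0554; it was called higher, at 0.11 and 0.13, without naive replicate 2 and resistant replicate 3). Mcl1 fell by 0.60 ± 0.0399 and Sqstm1, an autophagy receptor, rose by 0.50 ± 0.0396. Of the P-glycoprotein genes, Abcb1b fell from 151 ± 4.51 to 107 ± 3.95 CPM, and Abcb1a had 31 counts in naive and 37 in resistant libraries (adjusted p = 0.411).

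The largest rises by the naming rule were those of Morc1 (0.189 ± 0.0133 to 41.0 ± 0.773 CPM, 216-fold), Clvs1 (65.8-fold), Dennd2d (52.5-fold), Hspb8, a small heat shock protein (31.9-fold), Nlrp4c (26.3-fold), Epha7 (24.7-fold), Plcb4 (20.5-fold), Egln3 (19.5-fold), Camk2d (19.1-fold) and Adm2 (18.2-fold). The largest falls were those of Gpc5 (858-fold, to 4 counts), Igf2r (799-fold), Fndc1 (130.3-fold), Tex101 (45.0-fold), Klk8 (42.8-fold), Ripk3, a necroptosis kinase (42.6-fold), Ehf (40.2-fold), Dmrta2 (33.7-fold), Mat1a (32.6-fold) and Aldoc (26.7-fold). By the test, 4077 of 11974 genes were higher and 3974 lower in resistant 5TGM1, of which 439 and 736 changed at least 2-fold. In 8341 genes (69.7%) the libraries of the groups did not overlap, against 10% by chance. Of the 163 called genes among those named and the list members, 162 had all 3 resistant libraries on the same side of all 3 naive ones, the exception being Cd74 (0.10, adjusted p = 0.0477). The largest rises and falls were chosen for having no overlap, and only called genes were counted, so this was largely set by the choice. Reads on no annotated gene made up 10.8% ± 0.217 in naive and 11.7% ± 0.293 in resistant libraries (exact permutation p = 0.100). Of the lists, 8 were called by camera, and 1 with an estimated correlation.

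**Figure D1:**
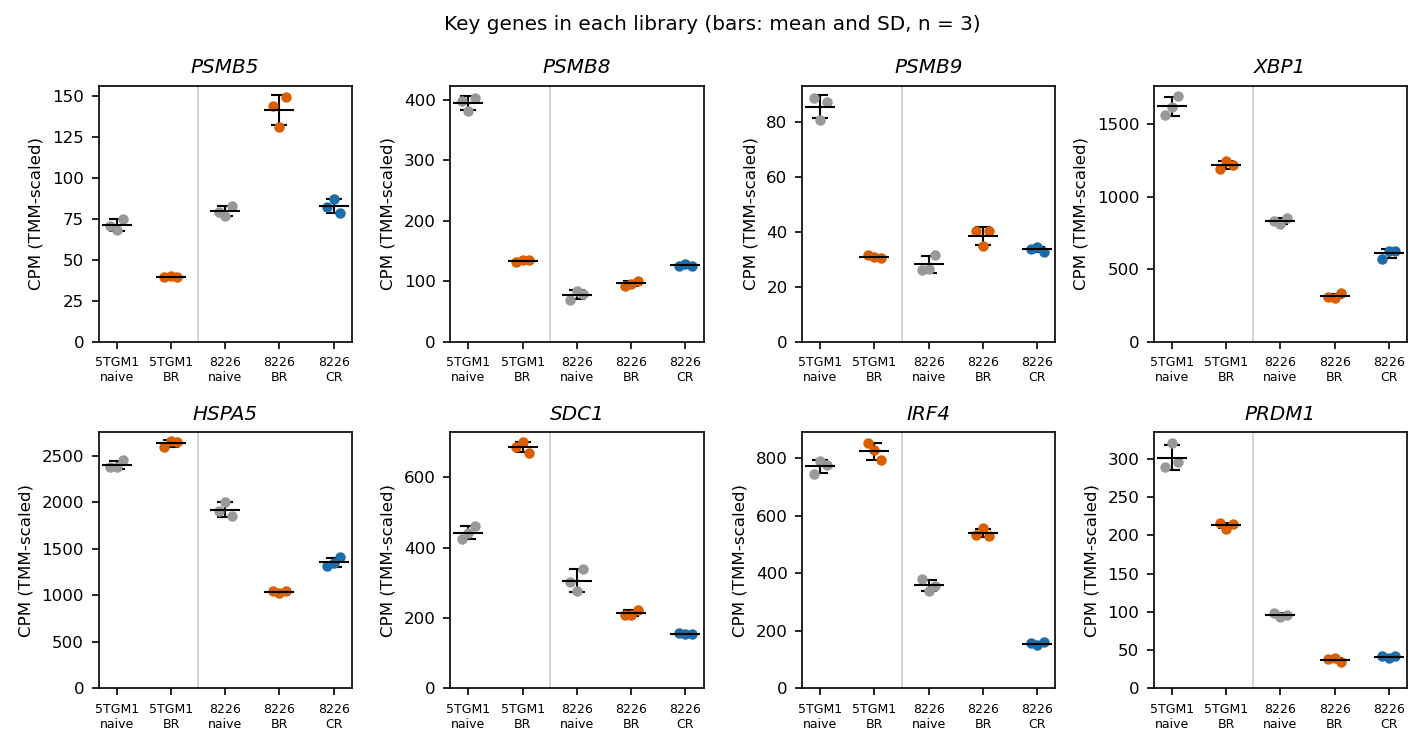
CPM (TMM-scaled) of PSMB5, PSMB8, PSMB9, XBP1, HSPA5, SDC1, IRF4 and PRDM1, or their mouse counterparts, in the 5 groups, with a point for each library and the mean ± SD of 3. Psmb8 lay at 395 and 134 CPM in naive and resistant 5TGM1, while PSMB8 lay at 78.1, 96.8 and 127 CPM in naive, bortezomib-resistant and carfilzomib-resistant 8226.

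The same question was then put to bortezomib-resistant and naive 8226 cells. Resistant 8226 cells held more transcript of MHC class II and interferon-induced genes, and less of unfolded protein response and adhesion genes. HLA-DRB1, an MHC class II chain, rose from 0.456 ± 0.0658 to 50.7 ± 2.99 CPM (6.79), and CXCL10, an interferon-induced chemokine, rose from 13.7 ± 0.838 to 636 ± 10.8 CPM (5.53). XBP1, a transcription factor of secretory cells, fell from 833 ± 20.7 to 316 ± 16.4 CPM (-1.40 ± 0.0567, adjusted p = 3.2e-12). PSMB5 rose 1.77-fold, from 79.7 ± 3.16 to 141 ± 9.12 CPM (0.83 ± 0.0605, adjusted p = 4.6e-09).

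All 12 MHC class II genes rose (median 5.02, or 5.01 with genes at 0 counts set to their bound; adjusted p = 1.5e-16, and adjusted p = 0.0217 with an estimated correlation), led by HLA-DQA1 (7.56), HLA-DRB1, HLA-DPB1 (6.46) and HLA-DPA1 (5.51), whose reads can be shared with close paralogs. Of the MHC class I and processing genes, 4 of 12 rose and 8 fell (median -0.42, adjusted p = 0.963). ERAP1, a peptide-trimming enzyme, rose by 1.37 and TAP1 by 0.70, while CALR fell by 0.97 and B2M by 0.86. Of the interferon-induced genes, 26 of 32 rose and 6 fell (median 0.81, adjusted p = 1.1e-05, and adjusted p = 0.0217 with an estimated correlation). GBP2, an interferon-induced GTPase, rose from 0.278 ± 0.0916 to 132 ± 3.35 CPM and XAF1 by 2.32. Of the NF-kB targets, 18 of 23 rose and 3 fell (median 1.06, adjusted p = 2.2e-05, and adjusted p = 0.0639 with an estimated correlation), with TNFAIP3 (3.23), CCL5 (2.66) and BIRC3 (1.98) up. Genes of the macrophage and monocyte list moved apart, as 5 of 9 rose and 3 fell (adjusted p = 0.445). EMR1 rose from 0.529 to 16.7 CPM and AIF1 from 2.96 to 25.2 CPM, while CD68 fell from 48.3 to 8.63 CPM. Of the fibroblast markers, 6 of 9 fell and 2 rose (adjusted p = 0.146), including CXCL12 (-3.44) and FN1 (-1.56).

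Of the constitutive 20S core genes, 13 of 14 rose and 0 fell (median 0.54, adjusted p = 0.0440, and adjusted p = 0.740 with an estimated correlation), led by PSMB2 (1.04), PSMB5, PSMB7 (0.79) and PSMA7 (0.72). Of the 19S cap genes, 13 of 22 rose and 5 fell (adjusted p = 0.445), with PSMC1 (0.68) and PSMC4 (0.63) up and PSMD6 (-1.09) and PSMD5 (-0.62) down. In the immunoproteasome list, PSMB9 (0.45 ± 0.0799) and PSMB8 (0.31 ± 0.0654) rose and PSME1 (-0.44) and PSME2 (-0.24) fell. Its median was -0.06 and its mean 0.00, the test pointed up, and the median turned to 0.12 when scaled by library size alone (adjusted p = 0.963). PSMB10 was at 47.3 ± 9.16 CPM in naive and 45.2 ± 4.30 CPM in resistant libraries (adjusted p = 0.609), and the call of PSME2 ended with library size alone (-0.06).

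Of the unfolded protein response genes, 28 of 33 fell and 3 rose (median -0.89, adjusted p = 2.2e-05, and adjusted p = 0.0217 with an estimated correlation). DERL3, a component of ER-associated degradation, fell by 2.41, the disulfide isomerase PDIA4 by 1.82, DNAJB9 by 1.64, EDEM1 by 1.62 and HSPA5 by 0.89 ± 0.0515 (adjusted p = 2.7e-10). Of the integrated stress response genes, 20 of 31 fell and 5 rose (median -0.37, adjusted p = 0.0457, and adjusted p = 0.151 with an estimated correlation). PHGDH, the first enzyme of serine synthesis from glycolysis, fell from 125 ± 1.85 to 0.0727 ± 0.103 CPM, and STC2 (-3.04), DDIT4 (-1.84) and ASNS (-1.29) fell. ATF4 fell by 0.30 ± 0.0630 (adjusted p = 0.000406), and DDIT3 was at 10.3 ± 0.795 and 11.4 ± 0.743 CPM (adjusted p = 0.179). With library size alone, ATF4 was no longer called (-0.12) and DDIT3 was called higher (0.34).

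Of the plasma cell identity genes, 14 of 21 fell and 5 rose (median -1.13, adjusted p = 0.0131, and adjusted p = 0.0928 with an estimated correlation). PRDM1 fell by 1.36, SDC1 by 0.52 ± 0.0652, CAV1 by 3.70 and TNFRSF13B by 2.58, while TNFRSF17, encoding BCMA, rose by 1.81 and IRF4 by 0.60 ± 0.0536. Of the B cell genes, 15 of 21 fell and 4 rose (median -2.24, adjusted p = 0.00428, and adjusted p = 0.0639 with an estimated correlation). BTK, a kinase of B cell receptor signalling, fell from 53.8 ± 3.94 to 0.617 ± 0.147 CPM and BLK by 2.32, FCER2 was left with 6 counts over the group, and CR2 had a naive to resistant ratio of 4049.6 (interval 727 to 159952). Of the adhesion and niche genes, 17 of 24 fell and 6 rose (median -1.74, adjusted p = 3.4e-05, and adjusted p = 0.0217 with an estimated correlation). NCAM1, encoding CD56, stood at 152 ± 4.64 CPM in naive libraries and at 3 counts in the resistant group, a ratio of 5443 (interval 1863 to 26395). The integrin subunit ITGA4 stood at 37.4 ± 3.10 CPM against 1 count, a ratio of 4032 (interval 724 to 159251). CCR2 fell from 43.4 to 0.0364 CPM and CD9 from 353 to 0.805 CPM.

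Of the cytosolic ribosomal protein genes, 50 of 55 fell and 1 rose (median -0.53, adjusted p = 0.0228, and adjusted p = 0.804 with an estimated correlation), including RPLP1 (-1.79), RPL4 (-1.36), RPS2 (-1.11) and RPLP0 (-1.03). Their share of reads was 5.63% ± 0.305 in naive and 4.22% ± 0.234 in resistant libraries (exact permutation p = 0.100, two-sided, the smallest that 3 against 3 allow). Of the MYC target and ribosome biogenesis genes, 23 of 28 fell and 1 rose (24 and 1 adjusted over the list alone) (median -0.54, adjusted p = 0.0194, and adjusted p = 0.151 with an estimated correlation), including SRM (-1.60), MRTO4 (-1.54), GNL3 (-1.40) and POLR1B (-1.39), and MYC fell by 0.38 ± 0.0482. Of the glycolysis genes, 14 of 24 fell and 2 rose (median -0.29, adjusted p = 0.0228, and adjusted p = 0.325 with an estimated correlation), including the glucose transporter SLC2A3 (-4.16), ENO2 (-4.04), SLC16A3 (-2.33) and PKM2 (-1.61). Of the cholesterol synthesis genes, 17 of 23 rose and 4 fell (18 and 4 adjusted over the list alone) (median 0.46, adjusted p = 0.00772, and adjusted p = 0.315 with an estimated correlation), including STARD4 (2.20), MVD (1.55), HSD17B7 (1.34) and MVK (1.31). Of the autophagy and aggresome genes, 19 of 28 rose and 6 fell (median 0.34, adjusted p = 0.0272, and adjusted p = 0.207 with an estimated correlation). GABARAPL1 (3.96), OPTN (1.88), VIM (1.47) and MAP1LC3B (1.10) rose, while SQSTM1 fell by 0.29 ± 0.0510. MCL1 was at 399 ± 12.7 and 416 ± 2.42 CPM (adjusted p = 0.263). With library size alone, SQSTM1 was no longer called (-0.10) and MCL1 was called higher (0.24). ABCB1, which encodes P-glycoprotein, had 6 counts over the naive libraries and 0 over the resistant ones, which allows up to 0.0300 CPM on library sizes without TMM scaling, and was not tested.

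Among the largest rises by the naming rule, ODZ3 (39.1 ± 2.53 CPM, at least 1578-fold), TBX18 (at least 588-fold) and ANGPTL1 (at least 563-fold) had 0 counts in naive libraries. UNC5C rose to 77.0 ± 1.79 CPM, the cancer-testis genes PASD1 and GAGE2A to 74.4 ± 0.634 and 27.6 ± 2.78 CPM, and the endogenous retroviral gene ERVV-1 to 35.5 ± 1.46 CPM, each from 4 or 5 counts. The ratio was 1038 (interval 287 to 8567) for NAA11 and 795 (interval 272 to 3857) for ANKRD22. The largest falls all ended at 0 counts: MYO10 (74.3 ± 4.87 CPM, at least 2673-fold), RNASE6 (at least 1738-fold), CDS1 (at least 1520.3-fold), NLGN1 (at least 1448-fold), UBE2QL1 (at least 1180.3-fold), ABHD10 (at least 1155-fold), SIGLEC7 (at least 1063-fold), SIAE (at least 947-fold), PRMT6 (at least 948-fold) and RHOBTB1 (at least 945-fold). By the test, 5314 of 13910 genes were higher and 5781 lower, of which 1824 and 2695 changed at least 2-fold. In 11079 genes (79.6%, against 10% by chance) the libraries of the groups did not overlap, and the 171 called genes among those named and the list members were all among them. For those 171 this was again largely set by how they were chosen. Scaling by library size alone shifted the median of all genes by 0.19 and gave 6665 genes higher and 4681 lower, so that 58.7% of calls were higher against 47.9% with TMM. The share of reads on no annotated gene moved with the group, from 11.5% ± 1.28 to 15.9% ± 0.888 (exact permutation p = 0.100). Of the lists, 14 were called by camera, and 4 with an estimated correlation (MHC class II, interferon response, unfolded protein response, and adhesion).

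Carfilzomib-resistant 8226 cells were compared with the same naive libraries. Plasma cell genes fell, and PSMB5 did not pass the test. IRF4, a transcription factor on which myeloma cells depend, fell 2.30-fold, from 358 ± 20.0 to 155 ± 5.44 CPM (-1.20 ± 0.0544, adjusted p = 2.0e-11), SDC1 fell from 306 ± 31.6 to 155 ± 1.68 CPM and PRDM1 from 95.9 ± 2.58 to 41.2 ± 1.41 CPM. CXCL10 rose from 13.7 ± 0.838 to 318 ± 9.95 CPM, while MX1, an antiviral GTPase, fell from 52.6 ± 0.517 to 4.86 ± 0.319 CPM.

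Of the plasma cell genes, 16 of 21 fell and 4 rose (median -1.09, adjusted p = 4.1e-06, and adjusted p = 0.0438 with an estimated correlation), and this was the only list whose call held with an estimated correlation. CAV1 fell by 4.80, ELL2, an elongation factor used in immunoglobulin secretion, by 2.51, and TNFRSF17 by 1.61, and ITGA4 had a naive to resistant ratio of 1895 (interval 648 to 9189). Of the adhesion and niche genes, 14 of 24 fell and 7 rose (median -0.46, adjusted p = 0.0133, and adjusted p = 0.182 with an estimated correlation). The tetraspanins CD81 and CD9 fell from 83.6 and 353 CPM to 0.122 and 3.13 CPM, and ITGB2 fell by 3.56. The macrophage marker ITGAM, encoding CD11b, rose from 5.21 to 158 CPM and EMR1 from 0.529 to 6.38 CPM, while CD68 fell from 48.3 to 13.7 CPM (3 of 9 rose and 5 fell, adjusted p = 0.620), and the stromal marker CXCL12 fell from 176 to 20.0 CPM.

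PSMB5 was at 79.7 ± 3.16 CPM in naive and 82.5 ± 4.28 CPM in carfilzomib-resistant libraries (0.05, 95% interval -0.08 to 0.18, adjusted p = 0.468). Of the 20S core genes, 8 of 14 fell and 2 rose (median -0.15, adjusted p = 0.998), with PSMB7 (-0.63) and PSMA2 (-0.50) down and PSMB4 (0.39) and PSMB2 (0.29) up. In the 19S cap, 5 of 22 rose and 6 fell (adjusted p = 0.998), and 7 and 6 did with library size alone; SHFM1 (-1.14), PSMD13 (-0.45) and PSMD8 (-0.45) fell and PSMD4 (0.47) rose. PSMB8 rose from 78.1 ± 7.64 to 127 ± 1.60 CPM (0.70 ± 0.0649) and PSMB9 by 0.25 ± 0.0793 (adjusted p = 0.00956), PSME1 (-0.59) and PSME2 (-0.39) fell, and PSMB10 was at 45.0 ± 3.01 CPM (adjusted p = 0.574). Without naive replicate 1, PSMB9 was no longer called (0.20).

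Of the unfolded protein response genes, 24 of 33 fell and 3 rose (25 and 3 adjusted over the list alone), and the list was not called (median -0.40, adjusted p = 0.0707). DERL2 (-1.16), HERPUD1 (-1.10), DERL3 (-1.05), SEL1L (-0.97), HSPA5 (-0.50 ± 0.0512) and XBP1 (-0.45 ± 0.0556) fell. ATF4 fell by 0.22 ± 0.0628 (adjusted p = 0.00551) and SQSTM1 by 0.30 ± 0.0509, and DDIT3 was at 10.1 ± 1.38 CPM (adjusted p = 0.773). Of the MHC class II genes, 10 of 12 rose and 0 fell (median 1.02, adjusted p = 0.176), including CD74 (0.63) and HLA-DRA (0.18, adjusted p = 0.0446). In the MHC class I list, 7 of 12 fell and 2 rose (adjusted p = 0.954); B2M (-0.55), TAPBP (-0.43) and CALR (-0.38) fell and TAP1 (0.37) rose. Of the interferon-induced genes, 11 of 32 rose and 16 fell, with a median of -0.12 and a mean of -0.15 where the test pointed up (adjusted p = 0.998); OAS3 rose by 2.93 and IFIT1 fell by 1.56. Of the ribosomal protein genes, 46 of 55 fell and 0 rose (47 and 0 adjusted over the list alone) (median -0.41, adjusted p = 0.108). MYC rose by 0.24 ± 0.0481 and MCL1 by 0.14 ± 0.0465 (adjusted p = 0.0126). ABCB1 had 3 counts over the carfilzomib-resistant libraries and was not tested.

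Among the largest rises, TBX18 had 0 naive counts (at least 601-fold), and PASD1 (122 ± 4.35 CPM), UNC5C (42.2 ± 0.636 CPM) and CAPN6 (23.2 ± 0.985 CPM) rose from 4 or 5. The ratio was 5333 (interval 957 to 210632) for SAGE1, another cancer-testis gene, 1799 (interval 323 to 71063) for FAM9B, 667 (interval 185 to 5512) for MUC15 and 475 (interval 163 to 2305) for TRPM6. PXDN (80.7 ± 5.27 CPM, at least 4085-fold), MAGED1 (at least 2909-fold), CACNG4 (at least 2107-fold), UBE2QL1 (at least 1664-fold) and SLC15A1 (at least 1552-fold) fell to 0 counts. SPP1, encoding osteopontin, fell from 619 ± 39.0 to 0.0328 ± 0.0212 CPM, and the ratio was 24471 (interval 4392 to 966542) for CD177 and 17351 (interval 3114 to 685330) for LBH. By the test, 4872 of 13910 genes were higher and 5100 lower, of which 1519 and 1863 changed at least 2-fold, and 10170 genes (73.1%, against 10% by chance) had no overlap. Scaling by library size alone turned the balance, with 5462 genes higher and 4589 lower. Of the 168 called genes among those named and the list members, 166 had no overlap, the exceptions being HLA-DRA and BAD, which again was largely set by the choice of genes. Reads on no annotated gene made up 11.9% ± 0.998 against 11.5% ± 1.28 in naive libraries (exact permutation p = 0.8). The number of lists called by camera, 2, rested on the libraries and the fit: it was 5 with the replicate number as a block and 4 without replicate 1 of the naive group.

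**Figure D2:**
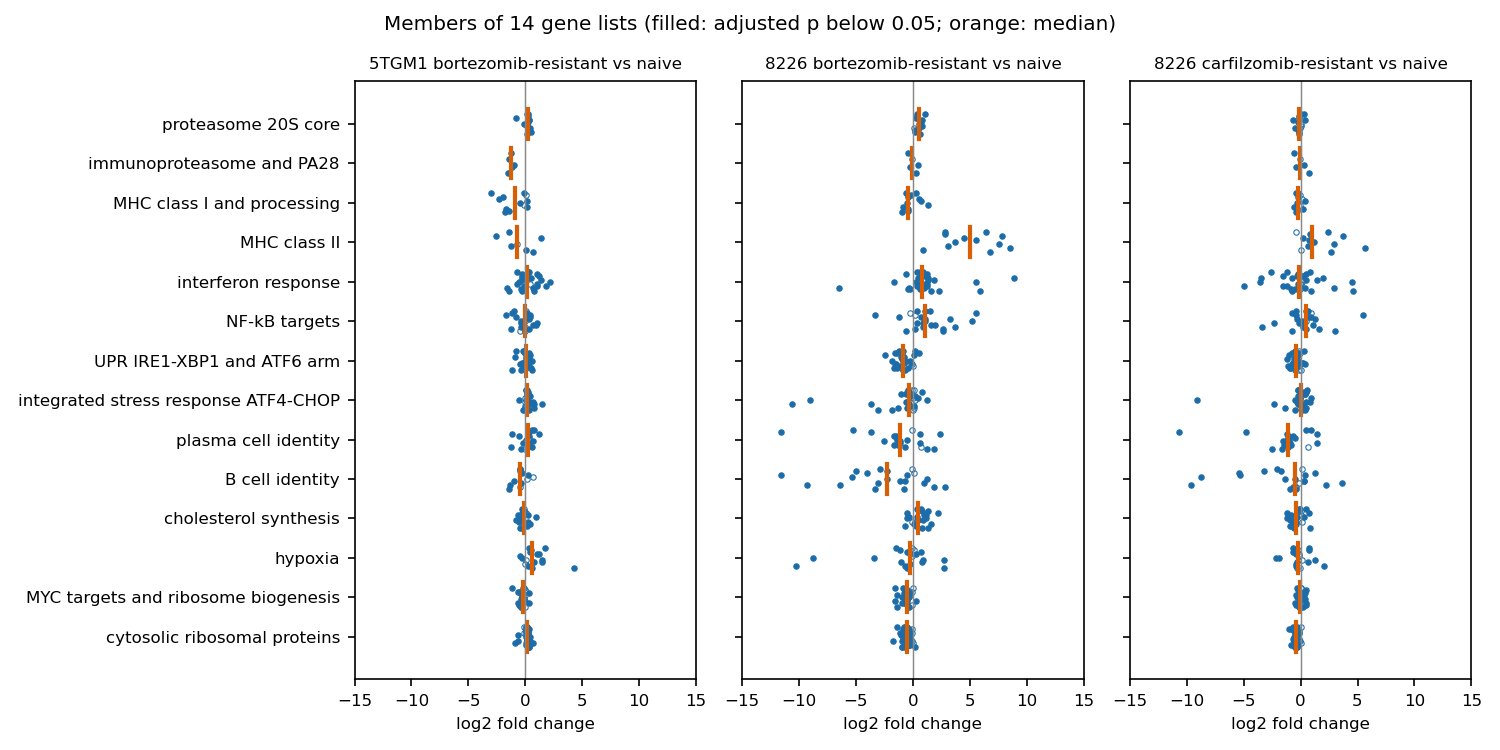
Log2 fold changes of the members of 14 gene lists in the resistant against naive comparisons (5TGM1 with bortezomib, 8226 with bortezomib, 8226 with carfilzomib). Each point is a gene, filled where its adjusted p was below 0.05, and the orange mark is the list's median, which for MHC class II lay at -0.68, 5.02 and 1.02.

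The resistant 8226 lines were compared directly; they had been kept in 10 nM of their drug and were 5 days off it. Carfilzomib-resistant cells held less transcript of interferon-induced genes than bortezomib-resistant cells. HLA-DRA was lower, at 13.5 ± 0.713 against 275 ± 7.67 CPM (-4.35), and PSMB5 was lower, at 82.5 ± 4.28 against 141 ± 9.12 CPM (-0.78 ± 0.0602, adjusted p = 1.0e-08). XBP1 was higher, at 609 ± 31.1 against 316 ± 16.4 CPM (0.95 ± 0.0562), and IRF4 lower, at 155 ± 5.44 against 541 ± 13.9 CPM (-1.80 ± 0.0552). In this comparison, rose and fell stand for higher and lower with carfilzomib than with bortezomib resistance.

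Of the MHC class II genes, 12 of 12 fell and 0 rose (median -3.65, adjusted p = 1.6e-15, and adjusted p = 0.0736 with an estimated correlation), including HLA-DPA1 (-4.77), HLA-DQA1 (-4.60) and HLA-DRB1 (-4.09). Of the interferon-induced genes, 25 of 32 fell and 5 rose (median -1.19, adjusted p = 5.3e-07, and adjusted p = 0.0276 with an estimated correlation), the only list whose call held with an estimated correlation. GBP2 fell by 6.91, MX1 by 4.74 and OASL by 2.90, while OAS3 rose from 0.0371 ± 0.0154 to 27.6 ± 0.374 CPM. Of the NF-kB targets, 15 of 23 fell and 5 rose (median -0.86, adjusted p = 0.0155, and adjusted p = 0.234 with an estimated correlation), with the anti-apoptotic BCL2L1 down (-2.71) and BCL2A1 up (5.32), TRAF1 down (-1.96) and IL10RA up (1.97). Of the cholesterol synthesis genes, 18 of 23 fell and 1 rose (median -0.78, adjusted p = 6.2e-06, and adjusted p = 0.133 with an estimated correlation), including MVD (-2.22), MSMO1 (-2.04), IDI1 (-1.76) and SC5DL (-1.48). Of the 20S core genes, 14 of 14 fell and 0 rose (median -0.56, adjusted p = 0.0176, and adjusted p = 0.719 with an estimated correlation), including PSMB7 (-1.43), PSMA7 (-0.93) and PSMA1 (-0.76). In the 19S cap, 13 of 22 fell and 6 rose (adjusted p = 0.434); SHFM1 (-1.26), PSMD7 (-0.83) and PSMC1 (-0.73) fell and PSMD6 (0.96) rose. PSMB8 rose by 0.39 ± 0.0646 (adjusted p = 5.2e-05) and PSMB9 fell by 0.20 ± 0.0785 (adjusted p = 0.0316), a call that ended without replicate 1 or 3 of either group (-0.16 and -0.16 for bortezomib, -0.19 and -0.17 for carfilzomib).

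Of the unfolded protein response genes, 25 of 33 rose and 5 fell (26 and 5 adjusted over the list alone) (median 0.58, adjusted p = 0.0256, and adjusted p = 0.133 with an estimated correlation), including EDEM1 (1.54), DERL3 (1.37), PDIA4 (1.33), P4HB (1.21) and HSPA5 (0.39 ± 0.0512). Of the integrated stress response genes, 19 of 31 rose and 4 fell (median 0.37, adjusted p = 0.0235, and adjusted p = 0.133 with an estimated correlation). PHGDH rose from a mean of 0.0727 to 132 CPM, STC2 by 2.52 and DDIT4 by 2.19, and PPP1R15A fell by 1.73. Of the serine, glycine and one-carbon genes, 13 of 18 rose and 3 fell (median 0.43, adjusted p = 0.0169, and adjusted p = 0.133 with an estimated correlation), including SLC1A4 (1.53), MTHFD1L (0.95) and PSAT1 (0.92). Of the MYC target genes, 23 of 28 rose and 2 fell (median 0.59, adjusted p = 0.0147, and adjusted p = 0.135 with an estimated correlation), including POLR1B (1.45), MRTO4 (1.44), RRP9 (1.37) and SRM (1.30), and MYC rose by 0.62 ± 0.0483. Of the autophagy and aggresome genes, 18 of 28 fell and 7 rose (median -0.28, adjusted p = 0.0235, and adjusted p = 0.234 with an estimated correlation). GABARAPL1 (-3.47), OPTN (-2.05) and PIK3C3 (-1.30) fell and WIPI1 (1.18) rose. Of the plasma cell identity genes, 10 of 21 rose and 8 fell, with a median of 0.13 and a mean of 0.04 where the test pointed down (adjusted p = 0.417); 8 rose and 8 fell with library size alone. ELL2 (-3.77), TNFRSF17 (-3.42) and SDC1 (-0.46 ± 0.0654) fell, and PRDM1 rose by 0.14 ± 0.0602 (adjusted p = 0.0437). That call ended with library size alone (0.02), with the replicate number as a block (0.14), and without replicate 1 or 3 of the bortezomib group (0.16 and 0.09) or of the carfilzomib group (0.14 and 0.13).

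Key genes that did not pass the test between the drugs were PSMB10 (-0.01, 95% interval -0.24 to 0.22, adjusted p = 0.959), SQSTM1 (-0.01, -0.12 to 0.10, adjusted p = 0.859), ATF4 (0.08, -0.05 to 0.22, adjusted p = 0.245), MCL1 (0.08, -0.01 to 0.18, adjusted p = 0.111) and DDIT3 (-0.18, -0.39 to 0.03, adjusted p = 0.104). DDIT3 and SQSTM1 were called lower with library size alone (-0.31 and -0.14), and DDIT3 without carfilzomib replicate 2 (-0.29). MAGEC1, a cancer-testis gene (86.5 ± 5.47 CPM, at least 3087-fold), SPG20 (at least 1775-fold), FAM133A (at least 1722-fold), SAGE1 (at least 1578-fold), ENAH (at least 1318-fold), CD300LF (at least 1107-fold), DUSP23 (at least 1102-fold), RNASE6 (at least 951-fold) and ANGPT1 (at least 928-fold) had 0 counts in bortezomib-resistant libraries. GNAI1 (31.9 ± 1.01 CPM with bortezomib resistance, at least 1613-fold), LPP (at least 1554-fold), SPATA6 (at least 948-fold), NAA11 (at least 866-fold), ANGPTL1 (at least 705-fold), CPLX1 (at least 676-fold) and GPER (at least 592-fold) had 0 counts in carfilzomib-resistant ones. By the test, 5549 genes were higher and 5141 lower with carfilzomib resistance, 2155 and 1729 of them at least 2-fold, and 11097 genes (79.8%, against 10% by chance) had no overlap. Of the 165 called genes among those named and the list members, 164 had no overlap, the exception being PSME2 (-0.15, adjusted p = 0.0376), whose call ended without replicate 1 or 3 of the bortezomib group (-0.11 and -0.15) or of the carfilzomib group (-0.13 and -0.10). Here too the choice of genes largely set the lack of overlap. Scaling by library size alone shifted the median of all genes by -0.12 and turned the balance, with 4693 genes higher and 6005 lower. Reads on no annotated gene moved with the groups, at 11.9% ± 0.998 with carfilzomib and 15.9% ± 0.888 with bortezomib resistance (exact permutation p = 0.100). Of the lists, 10 were called by camera, and 1 with an estimated correlation.

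The resistant 8226 lines were also compared by the genes that changed in both against naive libraries. PERP, a p53-induced membrane protein, rose from 0.182 ± 0.00694 to 61.6 ± 2.28 CPM with bortezomib and 60.0 ± 2.53 CPM with carfilzomib resistance, and the kinase MAP4K4 from 0.383 to 62.7 and 37.6 CPM. PALLD (7.29 and 7.86), LIN28B (7.88 and 7.00), MYO7B (8.17 and 6.70) and TTC39C (7.23 and 6.20) also rose in both. UBE2QL1, TMEM132E and ARHGEF4 had 0 counts in both resistant groups against 32.9, 16.9 and 13.9 CPM in naive libraries. Of 13910 genes, 5897 were called in the same direction (2669 higher and 3228 lower, where independent lists would share 1861 and 2119.6) and 2337 in opposite directions (3973 by independence). At a fold change of at least 2 in both, 2033 were shared and 462 changed in opposite directions. The log2 fold changes correlated across genes at 0.534, with a covariance of 3.26. In 20 simulations of unchanged groups against the same naive libraries, 0 genes were called in both, the mean correlation was 0.489 and the mean covariance 0.0103. Unchanged groups give almost no calls, so the 0 cannot gauge how many shared calls the naive libraries add in these data. Their fold changes are small too, so their covariance is small whatever the naive libraries add. The observed covariance lay above the highest simulated value, 0.0115, but for that reason cannot gauge sharing. The observed correlation, 0.534, was not far above the simulated mean of 0.489, and a correlation does not carry the size of the changes. Part of the excess of shared calls can come from the shared naive libraries, which do not divide into a pair of sets of at least 2 libraries each.

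**Figure D3:**
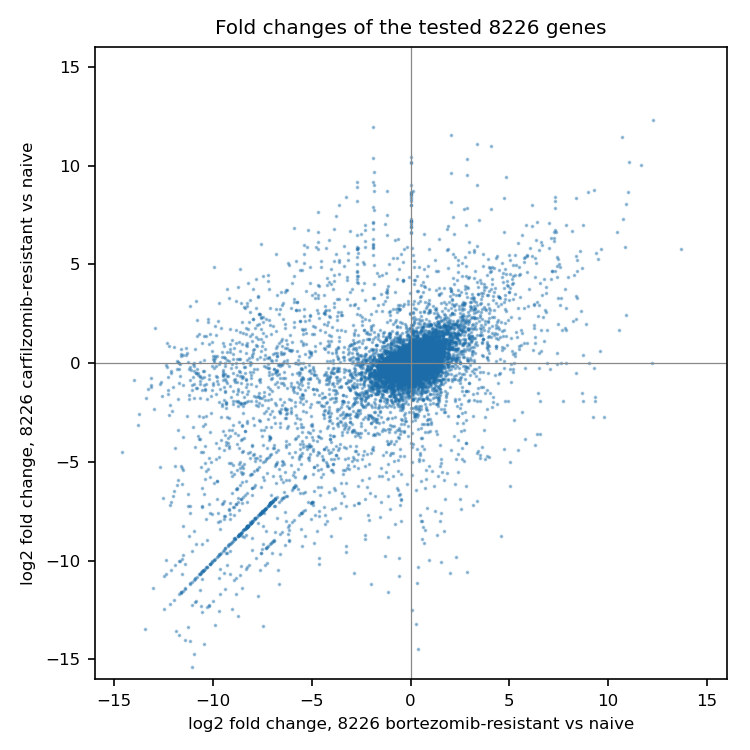
Log2 fold change against naive 8226 with bortezomib resistance (x axis) and with carfilzomib resistance (y axis), each point being 1 of 13910 genes (correlation across genes 0.534). The straight diagonal of points holds genes with 0 counts in both resistant groups, whose fitted values depend on the prior count.

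Across species, 8944 genes with shared symbols were tested in both lines. The phosphatase gene PTPN22 rose by 2.87 in bortezomib-resistant 5TGM1 and 3.70 in bortezomib-resistant 8226, and ADM2 (4.19 and 1.66), ADPRH (1.18 and 1.56), IFIT1 (1.20 and 1.13) and BNIP3 (1.48 and 0.93) rose in both. PIM2, a survival kinase of plasma cells (-1.29 and -1.30), GNL3 (-1.17 and -1.40), TRIM59 (-1.97 and -5.44) and SLC39A14 (-1.32 and -1.86) fell in both. In all, 2685 genes changed in the same direction: 1277 higher (1180.3 by independence, exact hypergeometric p = 5.6e-06) and 1408 lower (1249 by independence, exact hypergeometric p = 3.3e-13). Those p-values treat genes as independent draws, which they are not, so they can overstate the evidence for sharing. A further 2182 changed in opposite directions, and the log2 fold changes correlated across genes at 0.0415. At a fold change of at least 2 in both, 190 changed in the same direction (49 higher and 141 lower, against 19.7 and 57.6 by independence) and 159 in opposite directions (68.0 by independence). Between bortezomib-resistant 5TGM1 and carfilzomib-resistant 8226, 1925 genes changed in the same direction (969 higher and 956 lower, against 1089.7 and 1072 by independence) and 2443 in opposite directions (2161 by independence). At a fold change of at least 2 in both, 46 were higher and 97 lower in both (15.2 and 35.9 by independence), and 158 changed in opposite directions (48.0 by independence). BCAT1 (3.37 and 4.12) and EGLN3 (4.28 and 2.09) rose in both, and CSF2RB (-2.49 and -1.29) and LSP1 (-2.05 and -1.09) fell in both.

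The change with bortezomib resistance differed between the lines in 7689 of 11846 genes with shared symbols, where the log2 change in 8226 minus that in 5TGM1 was above 0 in 3647 and below 0 in 4042. PSMB5 fell in 5TGM1 and rose in 8226, a difference of 1.68 ± 0.0798 (adjusted p = 3.2e-13), and SDC1 rose in 5TGM1 and fell in 8226, a difference of -1.15 ± 0.0883 (adjusted p = 6.0e-10). The bortezomib dose also differed, at 20 nM in 5TGM1 and 10 nM in 8226. Species differed with the line, and a change particular to either resistant group cannot be told apart from an effect of resistance.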

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

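The tests of the strand column, of neighbouring genes and of other splits of the libraries for gene lists, overlaps and the difference between lines were set before their results were seen, and the other tests in this part were chosen after.

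Changes between bortezomib-resistant and naive groups that differed between the lines, by the test of the difference itself, are given here. Each is the log2 change in 8226 minus that in 5TGM1. They were 1.68 for PSMB5, 1.87 for PSMB8, 1.93 for PSMB9 and 0.90 for PSMB10. They were -0.98 for XBP1, -1.01 for HSPA5, -0.33 for ATF4, -0.29 for DDIT3 and -0.78 for SQSTM1. They were -1.15 for SDC1, 0.51 for IRF4, -0.85 for PRDM1, 0.67 for MCL1 and -0.22 for MYC. The largest adjusted p-values among them were those of DDIT3 (0.0179) and MYC (0.00531), and the dose differed between the lines.

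Reads on no annotated gene lie outside the measurements compared above and were raised over naive libraries in both bortezomib-resistant groups. They made up 11.7% in 5TGM1, where naive libraries had 10.8% (exact permutation p = 0.100, the smallest possible).

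In 8226 that share was 15.9% ± 0.888 with bortezomib resistance and 11.5% ± 1.28 in naive libraries. Genomic DNA would put reads on silent genes, but at equal depth the bortezomib-resistant group had 19.2% more genes without any count (7424 against 6227). The carfilzomib-resistant group also had more than naive libraries (6945), while its share was 11.9%. Genes that fell to 0 counts with resistance add to such numbers, so they cannot decide on genomic DNA, which stays open. Reads on the opposite strand of genes are argued against, since the excess was still 4.39 percentage points with both strands counted. Transcripts outside the annotation and intronic reads were not tested and stay open too, as does a difference that came with resistance.

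In 8226, genes at 10 CPM or more in naive libraries (those whose level could show a donor's sex left out) stood at 3 counts or fewer in all libraries of a resistant group in 149 cases with bortezomib and 43 with carfilzomib resistance, 33 of them shared (0.717 by independence). MAF, the oncogene highly expressed in 8226, kept at least 69.8% of its naive level, which argues against libraries of a line that lacks it, while with bortezomib and carfilzomib resistance known targets of MAF stood at 18.0% and 41.7% (ITGB7), 22.1% and 58.8% (CCR1), 67.3% and 60.0% (CCND2), and 117% and 147% (NUAK1). The choice of strand column is argued against, as 94.3% of these genes stayed under 1% of their naive level in the unstranded counts. Loss or silencing of blocks of neighbouring genes may account for part of the pattern but cannot be told apart from scattered loss: 8 neighbouring pairs, such as NXF3, TCEAL8 and TCEAL4, were found with bortezomib resistance (random median 2, permutation p = 0.00370) and 1 with carfilzomib (permutation p = 0.191). Fewer genes went the other way, to 10 CPM or more in a resistant group from 3 counts or fewer in all naive libraries. They numbered 8 with bortezomib and 5 with carfilzomib resistance, and the cause of this imbalance was not tested. Another line that expresses MAF, a subclone grown out under the drug and silencing with resistance were not tested and stay open.

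In bortezomib-resistant 5TGM1, MHC class I and immunoproteasome transcripts fell together. Reads shared between paralogous MHC genes concern the H2 family, so they do not bear on the other members, whose median log2 change was -1.17 (9 of 13 lower). For the 4 H2 members, all lower, such sharing cannot be told apart from a change in level because those reads were set aside in counting. A loss of macrophages from the cultures is argued against: their 17 markers had a median of 0.136 CPM in naive libraries, 14 of them under 1 CPM, where H2-K1 alone fell by 2783 CPM, and of the abundant ones Cd68 (0.49) and Mrc1 (0.40) rose. These CPM were scaled over all genes with counts, without the filter, so they differ slightly from the levels above. A general fall of interferon-induced genes is argued against, as 14 of 28 rose and 12 fell (median 0.19). A fall of some of them along with the class I genes is left open. A fall tied to Nlrc5 or to resistance itself stays open and was not tested.

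For the numbers of genes called in a comparison, 10 splits of the libraries cannot give a share under 0.05. The real numbers were 8051, 11095, 9972 and 10690 for 5TGM1, bortezomib-resistant 8226, carfilzomib-resistant 8226 and the resistant 8226 lines, and the highest others were 0, 0, 0 and 0. In each, 1 split, the real one, gave as many. For gene lists, 10 splits again cannot give such a share: the real numbers were 8, 14, 2 and 10, the highest others 10, 13, 7 and 11, and 2, 1, 10 and 3 splits gave as many. Other splits thus reached the real number in 5TGM1, carfilzomib-resistant 8226 and the resistant 8226 lines, the outcome set beforehand as a mark of chance. In bortezomib-resistant 8226 the real number, 14, was only just above the highest other, 13. Medians of the other splits were 6, 11, 5 and 8 lists in the order above, though these splits called 0 genes. List calls at the preset correlation thus arise without called genes. Their number sets the real groups little or not at all apart.

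For the results that join comparisons, 100 splits were fitted, most of which mix the groups and call few or no genes (median 0 in each). They bear on whether libraries of a group belong together more than on the sharing or the difference, for which chance is left open. Genes changed in the same direction in both resistant 8226 lines numbered 5897, reached by 1 of 100 splits, and the highest other, which mixed the groups, gave 5534. In both bortezomib-resistant lines they numbered 2685, reached by 1 of 100 pairs of splits, and the highest other, in which the real groups of 1 line were exchanged, gave 2182. Genes that differed between the lines numbered 7689, reached by 2 of 100 pairs, and that same exchange gave more, 7927.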

How the results depend on the processing

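The unstranded counts were chosen after the data were seen, and the other alternatives before. With a test against a fold change of 1.5, genes called higher and lower numbered 628 and 930 (5TGM1), 2513 and 3240 (bortezomib-resistant 8226), 1897 and 2247 (carfilzomib-resistant 8226), 2752 and 2415 (the resistant 8226 lines). With a fold change of at least 2 they numbered, in that order, 439 and 736, 1824 and 2695, 1519 and 1863, 2155 and 1729. Both settings ask for larger changes. Shared genes with at least that fold in both numbered 2033 in the resistant 8226 lines and 190 in the bortezomib-resistant lines. Gene lists called numbered 1, 4, 1 and 1 with an estimated correlation and 29, 34, 29 and 31 with fry. The fry test asks whether a list's own genes shift up or down, without setting them against other genes. For carfilzomib-resistant 8226, 4 lists were called without replicate 1 of the naive group, and the cause was not tested.

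Leaving out each library in turn gave 3756 to 4089 genes higher and 3652 to 4057 lower (5TGM1), 5122 to 5330 genes higher and 5646 to 5886 lower (bortezomib-resistant 8226), 4599 to 4937 genes higher and 4778 to 5180 lower (carfilzomib-resistant 8226), 5312 to 5735 genes higher and 4819 to 5310 lower (the resistant 8226 lines). Lists called were 6 to 9, 12 to 16, 2 to 4 and 10 to 12. Shared genes were 5606 to 5934 in the resistant 8226 lines and 2468 to 2699 in the bortezomib-resistant lines, and 7334 to 7830 genes differed between the lines. In the unstranded counts, 7922, 10954, 9819 and 10558 of the calls were kept in direction.

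The replicate numbers did not pair the libraries. Deviations from the group means correlated at -0.105 to -0.0338 between same-numbered 5TGM1 libraries and -0.0706 to 0.156 between 8226 ones, and 0 and 2 libraries were closest to their own number. With the replicate number as a block, genes called higher and lower numbered 3912 and 3804, 5322 and 5772, 4881 and 5105, 5551 and 5158, and lists numbered 9, 16, 5 and 11. The increase to 5 lists in carfilzomib-resistant 8226 was not tested for a cause. Shared genes numbered 5907 and 2562, and 7719 genes differed between the lines.

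Of 4564 alternatives to 344 values of named genes, 4516 kept their direction and call, 23 were no longer called, 7 became called and 18 changed sign. Every sign change was in a value that did not pass the test, and the cause was not tested. With library size alone, log2 changes were 0.124 for PSMB10 with bortezomib resistance and 0.0288 for DDIT3 with carfilzomib resistance in 8226, and -0.0418 for ATF4 and -0.0400 for MCL1 between the resistant lines. Leaving out each library, PSMB10 ran from -0.168 to 0.100 with bortezomib and from -0.173 to 0.0939 with carfilzomib resistance. It ran from -0.0710 to 0.0651 between the resistant lines, where the replicate block gave 6.7e-05. DDIT3 ran from -0.143 to 0.0355 with carfilzomib resistance. SQSTM1 ran from -0.0362 to 0.0265 between the resistant lines, and was 0.0161 in unstranded counts.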

Other observations

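The genes in this part were chosen after their values were seen. MET, the HGF receptor, rose from 0.200 ± 0.0987 CPM in naive to 34.7 ± 2.27 CPM in bortezomib-resistant and 4.12 ± 0.459 CPM in carfilzomib-resistant libraries, while HGF fell from 16.4 ± 0.354 to 0.0916 ± 0.0557 and 0.271 ± 0.0375 CPM. IGF1 rose from 0.702 ± 0.138 to 23.2 ± 2.54 CPM with bortezomib resistance and had 1 count over the carfilzomib-resistant libraries. IL6R rose from 114 to 357 CPM with carfilzomib resistance. The efflux transporter gene ABCG2 fell from 101 ± 2.27 to 0.157 ± 0.0535 CPM with bortezomib and 63.8 ± 0.982 CPM with carfilzomib resistance, and ABCA1, a cholesterol exporter, changed by 4.15 and -1.72.

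With bortezomib resistance BCL2 rose (0.85), and the pro-apoptotic BIK fell from 10.2 ± 0.892 to 0.0571 ± 0.0516 CPM and BCL2L11 fell by 1.30, while BCL2 fell with carfilzomib resistance (-0.77). As lists, neither side of the BCL2 family was called by camera with bortezomib resistance. Among pro-apoptotic members 6 of 12 rose and 4 fell (median 0.13, adjusted p = 0.993). Among anti-apoptotic members 5 of 11 rose and 3 fell (median 0.14, adjusted p = 0.445). The death receptor genes FAS (2.34 and 1.91) and TNFRSF10B (1.41 and 1.56) and the antibody target CD38 (0.65 and 1.44) rose in both resistant 8226 lines. FTL, the ferritin light chain, fell from 2933 to 702 and 1858 CPM. NQO1 rose with bortezomib (1.21) and fell with carfilzomib resistance (-0.70), where CCND1 rose (1.45).

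In the resistant lines together, 565 of 8944 genes with shared symbols were higher and 632 lower in all 3 comparisons with naive libraries, against 414 and 440.3 if these were independent. They were not, since both 8226 comparisons share their naive libraries. At a fold change of at least 2 in each, 22 were higher and 70 lower. In 5TGM1, bortezomib-resistant 8226 and carfilzomib-resistant 8226 the log2 changes were -4.74, -1.03 and -1.66 for ALDOC, -1.24, -1.32 and -2.18 for HIST1H1C and -1.14, -1.93 and -1.08 for BMP1.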
